A study of Homo sapiens with 4 samples.

How the data were processed

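Poly(A) RNA of 4 leiomyosarcoma lines (RKN, SKLMS1, SKN and SKUT1) was sequenced from untreated cultures, 1 library per line. Per the labels' protocols, cells grew in Dulbecco's modified Eagle's medium with 10% fetal bovine serum, RNA was isolated with RNeasy Plus columns, and libraries from the TruSeq Stranded mRNA kit were read on an Illumina NextSeq 500 as single-end reads of 75 bp. The submitters' processing notes name STAR, Cufflinks and the genome build hg19, with no version. The gene annotation, the strand setting of the quantification and the filters are not given in the sources used here. The deposited values are FPKM (fragments per kilobase of transcript scaled to library size) per gene symbol, made by the authors, in a single table of 4 columns. No annotation of hg19 was used here, so no coordinates are given.

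The table held 23610 rows. In 28 rows the gene symbol had been turned into a spreadsheet date number, and 5 further rows held 8 cells with a spreadsheet error. Both kinds were left out, and 23577 genes remained, with no symbol listed more than once. The columns summed to 446954 in RKN, 494047 in SKLMS1, 538300 in SKN and 619584 in SKUT1. A gene was kept for comparison when its FPKM was 1 or more in at least 1 line, which gave 13713 genes. Between 6793 and 7534 genes per line were listed at 0. RPS28, a ribosomal protein gene that every cell uses, was among them in SKUT1, so a value of 0 is reported only as listed at 0 and no fold is given for such a gene by name. Counts of genes and list medians include values of 0 as listed, so some members counted as lower can be failed estimates.

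Read totals are not part of the table, and depth was estimated from low values. For genes with a single transcript in GENCODE release 29 and an effective length from an assumed mean fragment length of 200 bases, the value of 1 read was read off the most frequent step. The resulting totals were 33600000 reads in RKN, 30700000 in SKLMS1, 25300000 in SKN and 24400000 in SKUT1. With them, 59.2 to 61.6% of the low values of 349 to 406 genes lay within 0.1 of a whole number of reads. A unit set independently of the values would give 20% by chance. As the unit was fitted to these low values, some excess was built in, and the comparison does not check the totals. These totals rest on an annotation that may not be the authors', and no counts were recovered from them.

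Each line was a group of 1 sample, so no test, p-value or standard error was computed. Values were compared as log2(FPKM + 1). For each of the 6 pairs of lines, Spearman's rho across the kept genes and the number of genes at least 4-fold apart (2 on the log2 scale) were computed. A gene counted as highest in a line when it exceeded the highest of the other 3 by at least 2 on that scale, and as lowest when it lay at least 2 below the lowest of them. For 38 gene lists fixed before the data were examined, the difference of each member from the mean of the other 3 lines was taken, members at 1 or more on the log2 scale (2-fold) were counted, and the median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Members without an FPKM of 1 in any line were not counted. Of the 152 medians, 75 lay below the 2.5 or above the 97.5 percentile, where 7.6 would if genes of a list did not vary together, which they commonly do. Median and mean differed in sign for 18 of the 152, and for these the text draws no direction. Percentiles describe these libraries only.

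The genes named in the text follow a rule that was also fixed before the data were examined. It took, for each line, the 12 genes with the widest gap above the other lines among those with an FPKM of 10 or more there, the 8 with the widest gap below among those with 10 or more in each other line, up to 6 members with the widest range from each list, and all members of the lists of recurrently altered and mismatch repair genes. Short and unplaced RNAs were left out of the first part, and some genes that the rule takes are not reported here. Other genes, chosen after their values were seen, are marked as such. Which genes neighbour each other was taken from the RefSeq annotation of assembly GRCh38.p14, in which 97.7% of the kept symbols were found, for order only.

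The code was tested on simulated data built from the mean levels of the 13713 genes, with 200 genes of a line shifted by 3.5 on the log2 scale and an assumed noise of SD 0.3. All shifted genes were recovered in each comparison of 1 line with the other 3, which checks the code only and, as the noise was not measured, gives no error rate for these libraries. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, rescaling of the columns to TPM, median-of-ratios scaling, quantile normalization, no filter or a minimum FPKM of 5, detection at 0.5 or 5, an 8-fold rule, Pearson's r, the median in place of the mean of the other lines, and leaving out each comparison line in turn. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.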

Results

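The data described the transcriptomes of 4 established human leiomyosarcoma lines, RKN, SKLMS1, SKN and SKUT1. Leiomyosarcoma is a malignant tumour of the smooth muscle lineage. Each line was represented by 1 poly(A) RNA-seq library from untreated culture, so each line was its own group and the labels gave no further contrast than the lines themselves. The estimated depth was 33600000 reads in RKN, 30700000 in SKLMS1, 25300000 in SKN and 24400000 in SKUT1. At these depths 1 read on a transcript of 2 kb was worth an FPKM of 0.0165 to 0.0228. Genes with an FPKM of 1 or more numbered 11460 in RKN, 11738 in SKLMS1, 11474 in SKN and 11518 in SKUT1, and the 100 most abundant genes held 30.0 to 35.7% of the summed FPKM. With 1 library per line, differences between lines have no replicate check, and all of them are given below as sizes without a test. Fold sizes are on the log2(FPKM + 1) scale, which understates the difference of low genes.

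SKUT1 was the line least like the other 3, with genes of connective tissue far above the other lines. COL1A2, a chain of type I collagen, had an FPKM of 5096 in SKUT1 against 98.3 in RKN, 77.5 in SKLMS1 and 0.113 in SKN. IL1B, a pro-inflammatory cytokine, separated SKN from the rest (1090 against at most 0.948), and ALDH1A1, which makes retinoic acid from retinaldehyde, separated RKN (1108 against at most 0.765). CD24, a surface glycoprotein, was 1079 in SKLMS1 and at most 17.1 elsewhere. Across the 13713 genes with an FPKM of 1 or more in at least 1 line, Spearman's rho ran from 0.682 for RKN and SKUT1 to 0.817 for SKLMS1 and SKN. The remaining pairs gave 0.739 for SKN and SKUT1, 0.753 for SKLMS1 and SKUT1, 0.774 for RKN and SKLMS1 and 0.780 for RKN and SKN. These are correlations across genes, which are not independent replicates.

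RKN and SKUT1 were also the pair with the most genes at least 4-fold apart, 2087, of which 690 were higher in RKN and 1397 in SKUT1. SKN and SKUT1 differed in 1658 genes (603 higher in SKN, 1055 in SKUT1) and SKLMS1 and SKUT1 in 1655 (657 higher in SKLMS1, 998 in SKUT1). RKN and SKLMS1 differed in 1342 genes (474 and 868), RKN and SKN in 1323 (530 and 793), and SKLMS1 and SKN in 1084 (590 and 494). The columns had unequal sums, yet the median difference of all genes from the other lines was -0.04 in RKN and -0.03 in SKUT1. Median-of-ratios scaling left it at -0.06 and -0.05. Rescaling each column to the same sum as TPM moved it by 0.28 to 0.24 in RKN and by -0.29 to -0.31 in SKUT1. Median-of-ratios scaling centres the typical gene by construction, and its factors were 0.973 to 1.018 here, so it is no independent check. Whether RKN and SKUT1 were offset thus depended on the scaling, and which scale is right cannot be told from these values. On the TPM scale the split of RKN against SKUT1 became 1415 and 1353, that of RKN against SKN 901 and 896, and that of SKLMS1 against SKUT1 1059 and 974.

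**Figure D1:**
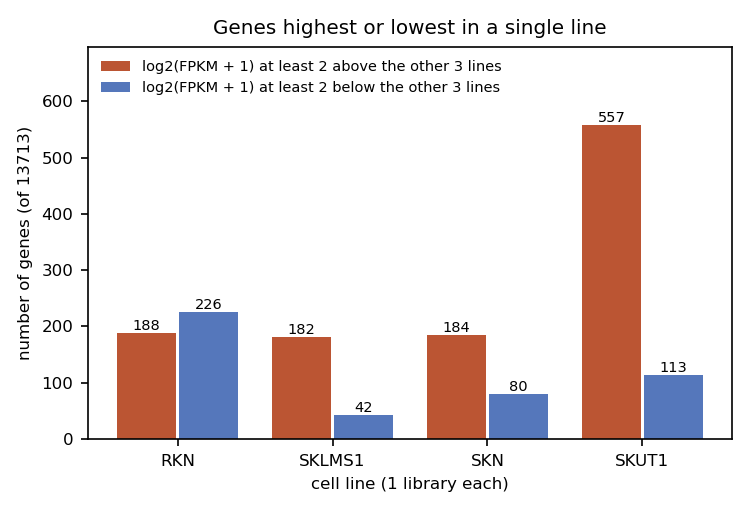
Number of genes, of 13713, whose log2(FPKM + 1) in a line lay at least 2 above the highest or at least 2 below the lowest of the other 3 lines (bars, 1 library per line). SKUT1 had 557 genes in the first class against 182 to 188 in the other lines, and RKN had 226 in the second class against 42 to 113.

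Matrix and fibroblast genes were the leading group in SKUT1. The 12 named genes with the widest gap above the other lines included POSTN (periostin, FPKM 2390 in SKUT1 and at most 2.11 elsewhere), COMP, a cartilage matrix protein (1120 against at most 0.330), and the small proteoglycan gene BGN (618 against at most 0.275). MFAP5, a microfibril component, was 851 in SKUT1 and listed at 0 in RKN, and PI16, a marker of adventitial fibroblasts, was 1155 and listed at 0 in SKLMS1 and SKN. SULF1 (797), CD248 (584) and SCUBE3 (514) were each at most 0.103 in the other lines. KRT14, a basal keratin that shares sequence with other type I keratins, was 474 in SKUT1, ACAN, the cartilage proteoglycan aggrecan, 403, and HSPB7, a small heat shock protein of muscle, 378, each with at most 0.0462 elsewhere.

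The fixed lists described the same line. In the list of fibrillar collagens and matrix, 35 of 38 measured members were at least 2-fold higher in SKUT1 than the mean of the other lines, with a median difference of 5.62 on the log2 scale. Examples were the elastin gene ELN (1624 in SKUT1, 22.7 in SKN, 0.0623 in SKLMS1 and listed at 0 in RKN), COL3A1 (1498, with 80.6 in RKN) and DCN, a collagen-binding proteoglycan (1064, with at most 2.88 elsewhere). No direction is given for COL1A1, listed at 0 in SKUT1 and 939 in SKLMS1, nor for FN1, the fibronectin gene, listed at 0 in SKUT1 and 2960 in SKN, as an exact 0 can be a failed estimate. Of the fibroblast and pericyte list, 19 of 25 members were higher in SKUT1 (median 3.50), among them ENG at 566, THY1 at 381, CXCL12 at 214 and the PDGF receptor gene PDGFRA at 136, which was at most 0.142 elsewhere. Basement membrane genes were higher in 12 of 20 (median 2.09; COL4A1 706 against at most 83.4), matrix proteases and their inhibitors in 16 of 24 (median 1.93; TIMP3 2838 against at most 18.6), and the TGF-beta and BMP pathway in 25 of 39 (median 1.98; the BMP antagonist GREM1 2390 against at most 140). Ligands of receptor tyrosine kinases were higher in 17 of 31 (median 1.41), with VEGFC at 152 and FGF7 at 64.2. All 6 of these medians lay above all 10000 random lists matched on expression.

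Genes of cell division were lower in SKUT1. Of 40 proliferation genes, 34 were at least 2-fold lower and none was higher (median -1.59), as with the spindle checkpoint gene CDC20 (18.4 against 149 to 223), UBE2C (48.2 against 280 to 498) and MYBL2 (9.61 against 57.5 to 151). The 8 named genes with the widest gap below the other lines were TNNT1, a slow skeletal troponin (2.63 against at least 93.8), ANXA3 (0.376 against at least 30.3), CDCA7 (0.224 against at least 17.5), IGF2BP3, an oncofetal RNA-binding protein (0.0929 against at least 12.8), CD70 (0.0578 against at least 12.1), MARCKSL1 (7.16 against at least 95.4), the peptide-trimming ERAP2 (0.315 against at least 13.2) and QPRT (1.42 against at least 24.6). SKUT1 was the highest line by at least 4-fold for 557 genes and the lowest for 113, a share of 83.1% highest among both, which was 70.5% after rescaling to TPM (543 and 227). Short or unplaced RNAs, of which a poly(A) library measures the short ones poorly, made up 13 of the highest and 34 of the lowest genes in SKUT1, 45 and 7 in RKN, 27 and 4 in SKLMS1 and 24 and 7 in SKN. The lowest count grew when a comparison line was left out, to 220 without RKN, 187 without SKLMS1 and 209 without SKN.

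**Figure D2:**
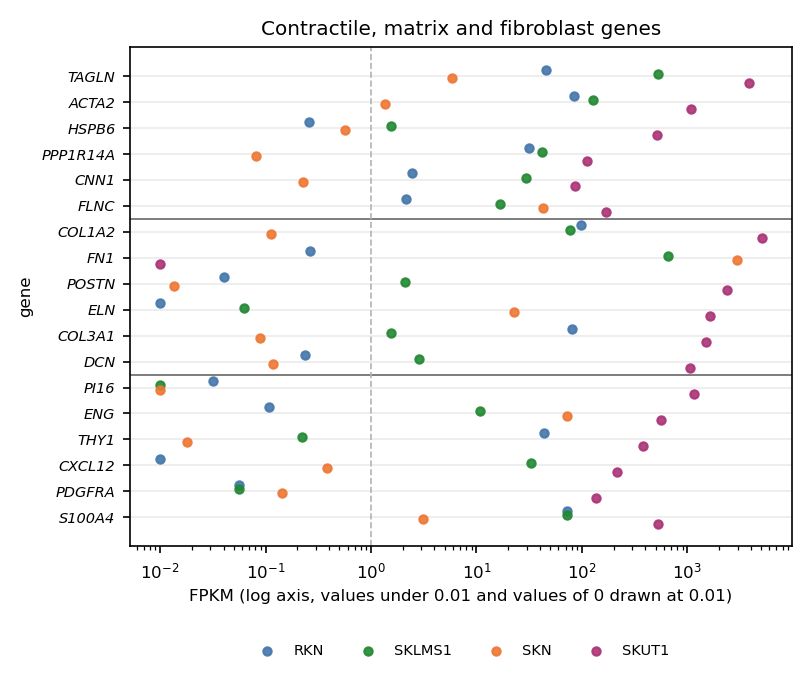
FPKM of the 6 members with the widest range from each of the contractile, matrix and fibroblast lists (log axis, 1 point per line, shifted vertically to avoid overlap). SKUT1 held the highest value of 17 of the 18 genes, and FN1 was the exception, listed at 0 there and at 2960 in SKN.

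SKN was set apart by inflammatory mediators. After IL1B, the granulocyte growth factor CSF3 was 373 in SKN and at most 0.0381 elsewhere, the neutrophil chemokine IL8 (CXCL8) was 642 against at most 9.96, and IL1A was 40.0 against at most 0.105. The collagenase MMP1 was 953 against at most 2.74, the decoy receptor TNFRSF6B 313 against at most 2.96, and BCL2A1, an anti-apoptotic BCL2 relative, 82.0 against at most 0.180. ALOX5AP, which serves leukotriene synthesis, was 108, the protease inhibitor SLPI 65.0 and listed at 0 in the other 3 lines, the endothelial receptor TIE1 70.0 and the Notch ligand DNER 160. Of 23 measured cytokines and chemokines, 17 were at least 2-fold higher in SKN and 4 lower, with a median of 3.93, above all 10000 random lists. CXCL1 was 641 in SKN and 43.8 in RKN, and the alarmin IL33 was 124 in SKN and 22.5 in SKUT1. IL32 went the other way, at 0.368 in SKN and 151 in SKLMS1. The same list had medians of -1.28 in RKN and -1.78 in SKLMS1, which were -0.13 and -0.48 once SKN was left out, and -2.15 in RKN without SKLMS1. In SKUT1 13 were lower and 6 higher (median -1.66, 0.02 without SKN, -2.54 without RKN and -0.82 without SKLMS1).

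The genes lowest in SKN included smooth muscle actin and a subunit of respiratory complex III. ACTA2, smooth muscle actin, was 1.37 in SKN against at least 84.7 in the other lines, and PPP1R14A, an inhibitor of myosin phosphatase, 0.0804 against at least 31.5. UQCRH, a subunit of respiratory complex III, was 0.493 against at least 160.6, and UQCRHL, a near-identical copy whose reads cannot be separated with certainty, was 0.119 against at least 100.7. COL1A2 was 0.113, the keratin gene KRT19 0.342 against at least 44.6, the inhibitor of differentiation ID2 0.918 against at least 50.5, and CREB3L1, a transcription factor of the secretory pathway, was listed at 0 against at least 36.8. In total 184 genes were highest in SKN and 80 lowest. The highest count was 302 without SKLMS1 and 318 without SKUT1, and the lowest was 231 without RKN, 171 without SKLMS1 and 151 without SKUT1.

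RKN was set apart by single genes of several kinds and by low matrix expression. Besides ALDH1A1, the retinol-binding protein gene RBP7 was 55.0 in RKN against at most 0.651, and the metallothionein genes MT1M and MT1A were 288 against at most 4.20 and 111 against at most 0.431. Metallothionein genes are near-identical, so the split among them is uncertain, and over the list of 29 metallothionein and oxidative stress genes 7 were higher in RKN and 10 lower (median -0.32, percentile 10.7). AXIN2, a feedback target of WNT signalling, was 60.0 against at most 1.48, the pericyte regulator RGS5 127 against at most 3.48, DDIT4L, an inhibitor of mTOR signalling, 121 against at most 1.73, MPP7 34.0 against at most 0.408 and PTPRZ1 23.5 against at most 0.163. PRAC (87.7) and the homeobox gene BARX1 (61.0) were listed at 0 in the other 3 lines, and GCG, the proglucagon gene, was 84.4 and listed at 0 in SKLMS1 and SKUT1. UBB, a polyubiquitin gene, was 0.232 in RKN against at least 551 in the other lines. GNG11 (0.0793 against at least 157), the proteoglycan genes SRGN (0.0659 against at least 96.1) and SPOCK1 (0.0705 against at least 47.6), the aldose reductase gene AKR1B1 (0.0746 against at least 73.7) and TGFBI (13.8 against at least 798) were also lowest there. TINAGL1 and the caveolar protein gene PRKCDBP were listed at 0 in RKN and were at least 85.7 and 71.2 elsewhere.

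In RKN 30 of 38 matrix genes and 15 of 20 basement membrane genes were at least 2-fold below the mean of the other lines (medians -3.37 and -2.21), with FN1 at 0.266, POSTN at 0.0406 and COL4A1 at 2.98. Another 5 matrix genes were at least 2-fold higher in RKN, and COL1A2 (98.3) and COL3A1 (80.6) were above their values in SKLMS1 and SKN. Matrix proteases were lower in 16 of 24 (median -1.82; MMP2 0.925), ligands of receptor tyrosine kinases in 20 of 31 (median -1.93; GAS6 5.13 against at least 12.9) and TGF-beta and BMP genes in 20 of 39 (median -1.02; INHBA listed at 0). Without SKUT1 these were -1.70 for matrix, -0.75 for proteases, -0.83 for ligands and -0.37 for TGF-beta and BMP. RKN had 188 highest and 226 lowest genes, 45.4% highest, and 56.1% on the TPM scale (318 and 249). The lowest count was 377 without SKLMS1, 430 without SKN and 346 without SKUT1.

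SKLMS1 had the fewest genes of its own below the other lines. KCNIP1, a modulator of potassium channels, was 154 there and at most 0.0456 elsewhere. FXYD2, a regulator of the sodium pump, was 95.3, PDZK1IP1 67.4, HAVCR1, a surface receptor of injured kidney epithelium, 104 and GPR15 34.8, with PDZK1IP1 and GPR15 listed at 0 in the other 3 lines. COL1A1 was 939 against 7.06 in RKN and 0.447 in SKN and was listed at 0 in SKUT1, so its place as highest in SKLMS1 is uncertain, since that 0 can be a failed estimate. The elongation factor gene EEF1A2 was 343 against at most 5.62, IL32 151 against at most 3.26, CRISPLD2 114 against at most 2.03 and the kinase gene DAPK1 67.7 against at most 0.826. Lowest were RCN3 (0.453 against at least 86.5), the ubiquitin hydrolase gene UCHL1 (0.601 against at least 75.2), DMKN (0.174 against at least 23.1) and glutamine synthetase, GLUL (0.571 against at least 20.4). MTAP of methionine salvage, FUOM, IL13RA2 and the WNT antagonist SFRP1 were listed at 0 there and were at least 14.6, 12.9, 11.9 and 10.1 elsewhere. The counts were 182 highest and 42 lowest. The highest count was 299 without SKN and 351 without SKUT1, and the lowest 157 without RKN, 124 without SKN and 92 without SKUT1.

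The smooth muscle programme differed between the lines. Of 35 measured contractile genes, 21 were at least 2-fold higher in SKUT1 (median 1.49) and 15 in SKLMS1 (median 0.80), while 21 were lower in RKN (median -1.17) and 18 in SKN (median -1.01). TAGLN, an actin-binding protein of smooth muscle, was 3816 in SKUT1, 531 in SKLMS1, 45.5 in RKN and 5.82 in SKN, and CNN1, calponin, followed the same order at 86.4, 29.6, 2.45 and 0.228. HSPB6 was 512 in SKUT1 and at most 1.55 elsewhere. FLNC, a muscle filamin, did not follow it, with 42.7 in SKN and 16.6 in SKLMS1. All 4 medians lay outside the range of the 10000 random lists. Leaving out single lines moved them to -0.67 (RKN without SKUT1), -1.85 (RKN without SKN), -0.46 (SKN without SKUT1) and 0.95 (SKUT1 without RKN), and for SKLMS1 to 0.42 without RKN, 0.34 without SKN and 1.27 without SKUT1.

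Transcription regulators of smooth muscle were closer together, with 14 of 33 higher in SKUT1 (median 0.48, percentile 99.1) and 8 lower in RKN (median -0.57, percentile 0.35, and -0.24 without SKUT1). The mesenchymal homeobox gene PRRX1 was 115 in SKUT1 and at most 0.117 elsewhere, KLF4 59.5 and GATA6 15.1. CSRP2, a LIM protein, was 155 in RKN, 158 in SKLMS1, 27.3 in SKUT1 and 5.21 in SKN, and TWIST1 was 80.4 in RKN and at most 10.6 elsewhere. MYOCD, the coactivator of smooth muscle genes, was 5.16 in SKUT1 and at most 0.0303 in the other lines. Of 32 skeletal muscle genes only 5 reached an FPKM of 1 in any line, with medians from -0.64 to 0.60 and percentiles from 9.21 to 87.8. They were TNNT1, ACTC1 (8.91 in SKUT1), PAX3 (3.72 in RKN and listed at 0 elsewhere), TNNT3 (2.81 in SKUT1 and listed at 0 elsewhere) and DES, the desmin gene, at most 1.10 in all lines.

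Uterine, Mullerian and hormone receptor genes gave no shared picture. PAX8, a transcription factor of the Mullerian tract, was 195 in SKN and 48.1 in SKLMS1 and at most 2.14 in the others. NR2F1, an orphan nuclear receptor, was 69.6 in RKN, the oxytocin receptor gene OXTR 38.3 in SKUT1, STC1 48.3 in SKN and the glucocorticoid receptor gene NR3C1 61.8 in SKUT1 and 4.78 in RKN. Of 23 measured members, 11 were lower in RKN (median -0.94, percentile 0.05) and 11 higher in SKUT1 (median 0.48, percentile 98.2). The RKN median was -0.34 without SKUT1, and the SKUT1 median was 1.20 without SKN.

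**Figure D3:**
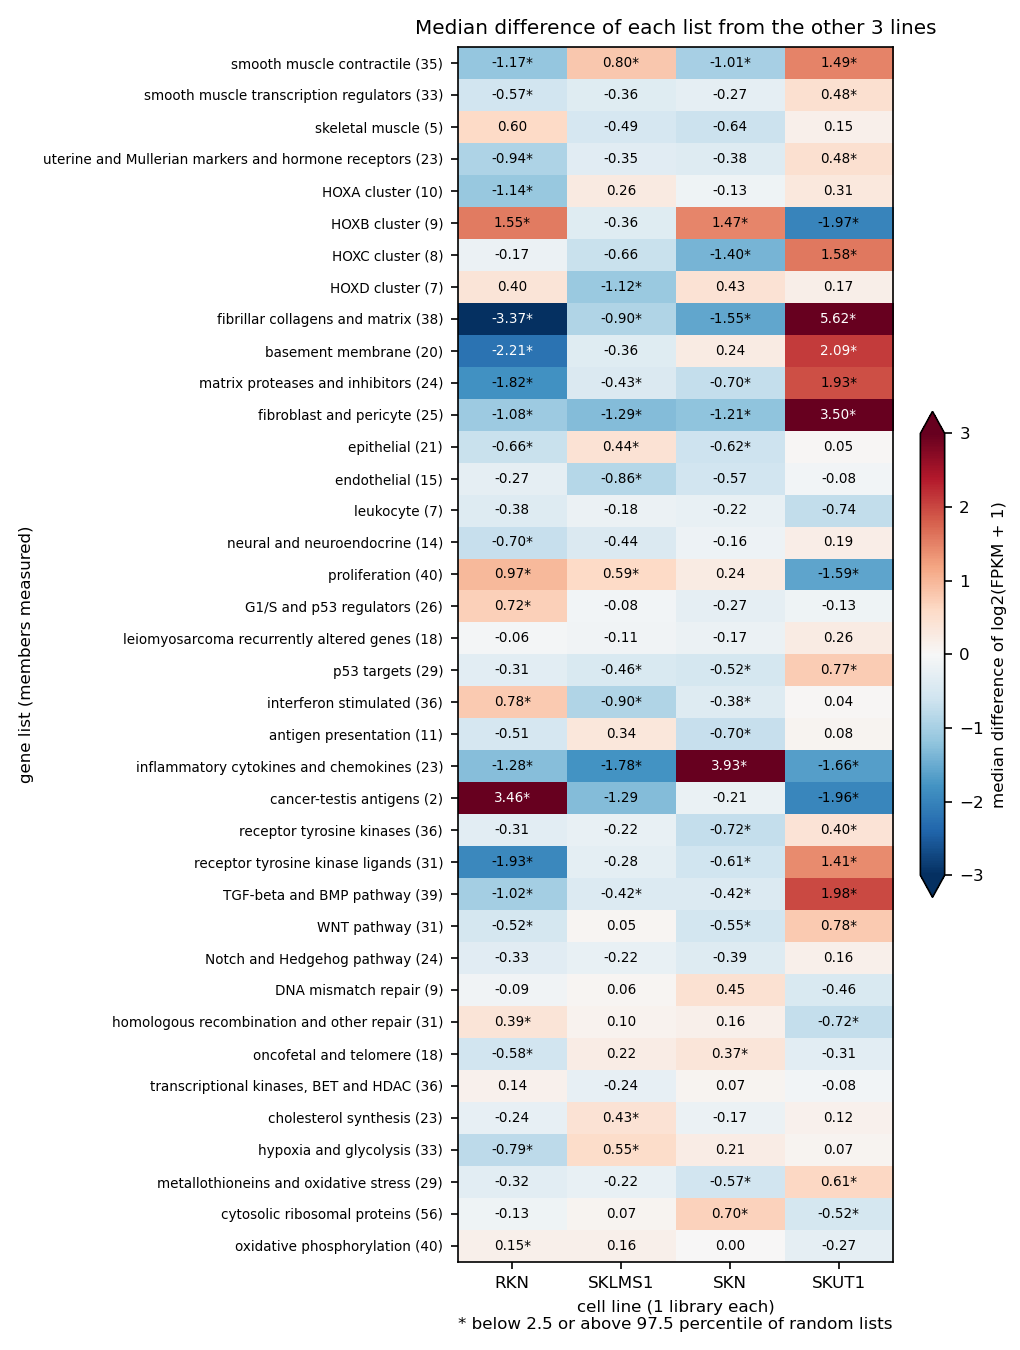
Median over each fixed gene list of log2(FPKM + 1) in a line minus the mean of the other 3 lines (colour and number, measured members in parentheses), with a star where the median lay below the 2.5 or above the 97.5 percentile of 10000 random lists matched on expression. The strongest colours are matrix (5.62) and fibroblast genes (3.50) in SKUT1, cytokines (3.93) in SKN, and matrix (-3.37) and the 2 measured cancer-testis antigens (3.46) in RKN. Rescaling the columns to TPM turned the sign of 17 of the 152 values, quantile normalization of 4 and median-of-ratios scaling of 1, and the signs of these 5 stayed as shown.

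Genes recurrently altered in leiomyosarcoma differed at single loci. RB1, the retinoblastoma tumour suppressor, was 0.752 in RKN and 11.7 to 18.8 in the other lines. CDKN2A, which encodes inhibitors of the RB and p53 pathways, was 326 in RKN, 16.4 in SKUT1, 0.549 in SKLMS1 and 0.125 in SKN. The cyclin gene CCNE1 was 29.0 in RKN and at most 7.73 elsewhere. DMD, the dystrophin gene, was 0.00680 in RKN and 2.22 to 10.1 elsewhere, and HMGA2, an oncofetal chromatin protein, was 50.4 in SKN and 2.22 in SKLMS1. The helicase gene ATRX lay between 7.10 and 9.84 and the Mediator gene MED12 between 4.82 and 6.60. NF1, MAP2K4, DLEU1, TSC1, TSC2 and BRCA2 each differed by at most 2.11-fold in FPKM between the extreme lines, PLAG1 was at most 2.24, and TERT, the telomerase catalytic subunit, was at most 1.53 and listed at 0 in SKUT1. Over the 18 measured members the medians lay between -0.17 and 0.26, within the central 95% of random lists.

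Of 26 regulators of G1/S and p53, 9 were at least 2-fold higher in RKN (median 0.72, percentile 99.99), where the kinase gene CDK6 was 0.164 against 12.1 to 14.2. In SKUT1 the p53-induced inhibitor CDKN1A was 348 against at most 12.8, and the cyclin gene CCND1 was 537 against 31.9 to 111. CDKN1C was 24.3 in SKN and 0.184 in SKUT1. The list medians of the other lines were -0.08 in SKLMS1, -0.27 in SKN and -0.13 in SKUT1, within the central 95% of random lists. Of 29 p53 targets, 11 were higher in SKUT1 (median 0.77, percentile 99.96), with the stress cytokine gene GDF15 at 52.3 against at most 1.70, TRIM22 at 18.5 and PHLDA3 at 75.9, whereas the death receptor gene FAS was 40.5 in SKUT1 and 37.9 in RKN. The p53 target medians of -0.46 in SKLMS1 and -0.52 in SKN were -0.06 and 0.03 without SKUT1. Without the SKN library the SKLMS1 value was -0.73, and the SKN value was -0.78 without SKLMS1.

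**Figure D4:**
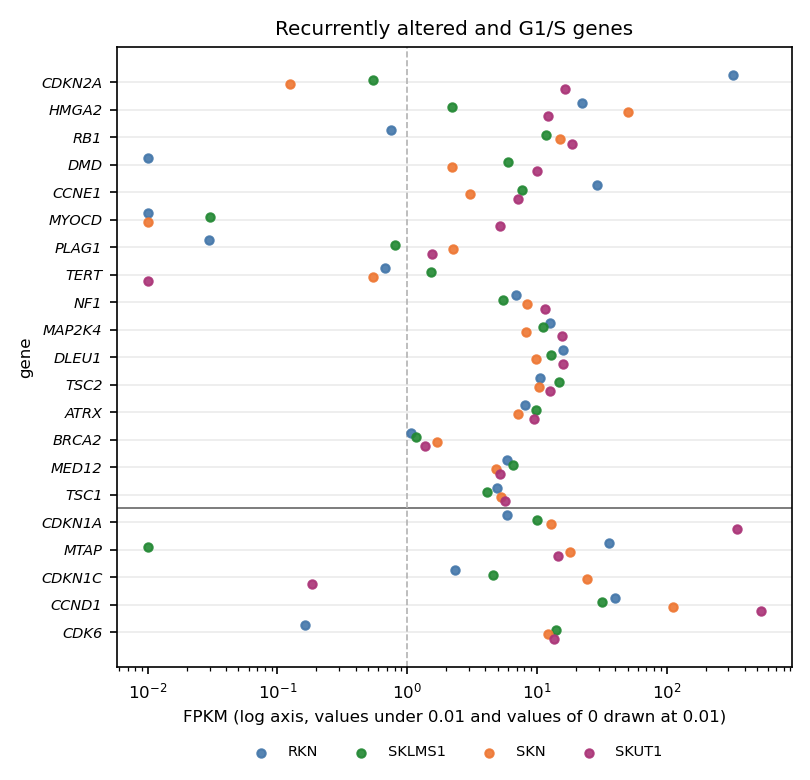
FPKM of 16 of the 18 measured genes recurrently altered in leiomyosarcoma and, under the line, the further G1/S regulators with the widest range (log axis, 1 point per line, shifted vertically to avoid overlap). CDKN2A ran from 0.125 in SKN to 326 in RKN, and RB1 was 0.752 in RKN against 11.7 to 18.8.

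Proliferation genes were higher than the mean of the other lines in RKN (19 of 40, median 0.97) and SKLMS1 (6 of 40, median 0.59), both above all random lists. Without SKUT1 these medians were 0.35 and -0.11, so the SKLMS1 value rested on the low SKUT1 library, and the SKLMS1 value was 0.93 without RKN. The mitotic kinase genes PLK1 and AURKA were 116 and 55.6 in RKN, 75.5 and 73.7 in SKLMS1, 58.9 and 115 in SKN, and 12.3 and 12.7 in SKUT1. Homologous recombination and other repair genes had a median of -0.72 in SKUT1 (11 of 31 lower, percentile 0.01) and 0.39 in RKN (9 of 31 higher, percentile 98.3, and 0.25 without SKUT1), with RECQL4 at 3.38 and 34.9 and RAD54L at 2.79 and 20.9.

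The median of the mismatch repair list set no line apart from random lists. MSH6, which takes part in the recognition of mismatches, was 23.1 in SKUT1 and 39.6 in RKN. MSH3 was 5.36 to 13.2, PMS2 4.58 to 9.14, PMS1 5.27 to 9.17 and MLH3 2.29 to 7.30. The exonuclease gene EXO1 was 6.44 in SKUT1 and 21.4 in RKN, and EPCAM was at most 1.80. The list medians lay between -0.46 and 0.45, within the central 95% of random lists.

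Interferon-stimulated genes were higher in RKN in 16 of 36 (median 0.78, above all random lists) and lower in SKLMS1 in 16 of 36 (median -0.90, and -0.38 without RKN). The membrane antiviral genes IFITM1 and IFITM2 were 149 and 320 in RKN and 4.13 and 10.2 in SKLMS1, IFI6 was 284 and 13.0, and the RNA sensor IFIH1 26.3 and 0.745. IFITM2 was not particular to RKN, as it was 298 in SKUT1. In SKN 9 were lower and 3 higher (median -0.38, percentile 0.93, 0.13 without RKN and -0.81 without SKLMS1), and ISG20 was among the higher (53.9 against at most 5.41). Among 11 measured antigen presentation genes, the medians were -0.51 in RKN, 0.34 in SKLMS1, -0.70 in SKN and 0.08 in SKUT1, and only the SKN value (percentile 1.05) lay outside the central 95% of random lists. It was -0.24 without SKLMS1 and -0.46 without SKUT1. HLA-B was 0.209 in SKUT1 against at least 7.46 in the other lines. HLA genes are polymorphic and alike, so their values are uncertain. HLA-E, HLA-G, TAP1, TAPBP, PSMB8 and PSMB9, chosen after their values were seen, were listed at 0 in all lines. TAP1, TAPBP, PSMB8 and PSMB9 are not HLA genes, so likeness among HLA genes does not account for their zeros. Such zeros can be failed estimates, and the list medians rest on the members that were left. Of the immune checkpoint ligands, PDCD1LG2 was 19.7 in SKUT1, 10.4 in SKN and 0.147 in RKN, and CD274 was at most 4.73. Of the 39 cancer-testis antigens in the table only PRAME and DDX43 reached an FPKM of 1, both highest in RKN (45.3 and 5.16, median 3.46, percentile 99.5, and 0 with no filter on low values).

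Markers of other cell types were mixed. Of 21 epithelial genes, 7 were higher in SKLMS1 and 2 lower (median 0.44, percentile 99.1). In SKUT1 7 were higher and 6 lower (median 0.05, percentile 75.4, and below 0 on the TPM scale), and KRT14, the desmosome gene DSP (201) and KRT7 (141) were highest there, while KRT8 was 268 in SKLMS1 and 265 in SKN and the claudin gene CLDN1 109 in SKN. The SKLMS1 median was 0.21 without RKN, 0.11 without SKN and 0.77 without SKUT1. The epithelial medians were -0.66 in RKN (percentile 1.10) and -0.62 in SKN (percentile 0.37), and the RKN value was -0.42 without SKUT1 and -0.39 without SKLMS1. Endothelial genes were lower in SKLMS1 in 7 of 15 (median -0.86, percentile 0.095). They were otherwise carried by single genes, with TIE1 at 70.0 in SKN, and TEK, CLEC14A and ERG at 39.6, 19.2 and 7.07 in SKUT1. Of 24 leukocyte genes 7 were measured, with medians from -0.74 to -0.18 inside the central 95% of random lists, and LAPTM5 at 37.3 in SKN and CD68 at 75.3 in SKUT1 were the most abundant of its widest-ranging members. Of 14 neural and neuroendocrine genes, 4 were lower and 3 higher in RKN (median -0.70, percentile 0.77, and -0.27 without SKN or -0.25 without SKUT1). L1CAM was 74.3 in SKN, 34.7 in SKLMS1 and 1.16 in RKN, whereas INA (17.0) and NES (10.3) were highest in RKN.

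The matrix and protease medians of SKLMS1 and SKN depended on which lines served for comparison. The protease gene ADAMTS1 was 16.6 in SKLMS1 and 8.88 in SKN against 0.0466 in RKN and 707 in SKUT1, whereas COL1A2 was lower in both than in RKN. The medians of the matrix list were -0.90 in SKLMS1 and -1.55 in SKN, 1.07 and 0.03 without SKUT1, -2.31 and -2.86 without RKN, and -1.56 in SKLMS1 without SKN. Those of the protease list were -0.43 and -0.70, 0.34 and 1.01 without SKUT1, and -1.38 and -1.15 without RKN. The fibroblast and pericyte medians of RKN, SKLMS1 and SKN were -1.08, -1.29 and -1.21, which without SKUT1 were -0.07, -0.14 and 0.00, and without SKLMS1 those of RKN and SKN were -1.71 and -1.87.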

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

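Under all settings SKUT1 had the most highest genes and RKN the most lowest, RKN and SKUT1 were the pair furthest apart and SKLMS1 and SKN the closest, while the order of the lines and pairs between these changed with the pseudocount and the scaling. Of 170 alternative values of counts and correlations, 111 stayed within 1.5 times or, for correlations, within 0.1, and 59 did not. Of 1672 alternative list medians 1493 moved by less than 1.5-fold, 177 by more, and 2 changed sign from a size of 1 or more, and of 640 gaps of named genes 424 stayed and 216 moved. The 2 sign changes from that size were the matrix list in SKN (main -1.55), from -2.86 without RKN to 0.031 without SKUT1, and the cytokine list in SKUT1 (main -1.66), from -2.54 without RKN to 0.022 without SKN, as fewer lines then set the mean. A median near 0 can change sign and still move by less than 1.5-fold, so the 1493 do not show that directions held. Of 152 medians, 17 changed sign under TPM, 4 under quantile normalization and 1 under median-of-ratios scaling. At 8-fold, 85 genes were highest in RKN, 79 in SKLMS1, 74 in SKN and 270 in SKUT1, and 88, 15, 32 and 44 lowest, a stricter rule by construction. With a pseudocount of 0.1 the pairs differed in 2511 (RKN and SKLMS1), 2474 (RKN and SKN), 3492 (RKN and SKUT1), 1966 (SKLMS1 and SKN), 2837 (SKLMS1 and SKUT1) and 2782 genes (SKN and SKUT1), the highest counts were 400 in RKN, 349 in SKLMS1 and 297 in SKN, and the lowest 526, 145, 220 and 372 (SKUT1). With a pseudocount of 5 the pairs gave, in the same order, 512, 535, 973, 447, 735 and 822, the highest counts 67, 75, 91 and 305, and the lowest 69, 7, 24 and 44. Without a filter rho was 0.890 for RKN and SKLMS1, 0.887 for RKN and SKN, 0.858 for RKN and SKUT1, 0.886 for SKLMS1 and SKUT1 and 0.880 for SKN and SKUT1, since genes near 0 in all lines then enter, and with a minimum FPKM of 5 it was 0.581 for RKN and SKUT1. On the TPM scale 318 genes were highest in RKN and 227 lowest in SKUT1; the cause was not tested beyond the unequal column sums. Leaving out a comparison line gave 255 to 282 highest and 346 to 430 lowest genes in RKN, 261 to 351 and 92 to 157 in SKLMS1, 247 to 318 and 151 to 231 in SKN, and 685 to 760 and 187 to 220 in SKUT1, because fewer lines set the bound. Median-of-ratios scaling and quantile normalization left all of their counts within 1.5 times. Depth limits the values near the worth of 1 read, 0.0165 to 0.0228 FPKM on a transcript of 2 kb, so values of 0.01 to 0.1 rest on few reads.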

Other observations

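The tests of explanations in this part were chosen after the results had been seen, unlike the gene lists. HOX genes, which record position along the body axis, differed by cluster. Of 9 measured HOXB genes, 8 were at least 2-fold lower in SKUT1 (median -1.97), and 8 were higher in RKN (median 1.55) and in SKN (median 1.47), with HOXB7 at 22.0 in RKN, 36.6 in SKN, 10.9 in SKLMS1 and 0.282 in SKUT1. HOXB13, a gene of the posterior end, was 9.49 in RKN and at most 0.882 elsewhere. Of 8 HOXC genes, 6 were higher in SKUT1 (median 1.58; HOXC10 55.9 against at most 9.03, HOXC8 33.7 against at most 1.72) and 6 lower in SKN (median -1.40, and -0.94 without SKUT1). HOXD genes were lower in SKLMS1 in 4 of 7 (median -1.12), but of these 4 only HOXD8 (0.0231) had a value there and HOXD4, HOXD9 and HOXD11 were listed at 0, which leaves the count uncertain. HOXA genes were lower in RKN in 5 of 10 (median -1.14), with HOXA3 at 0.281 against 11.5 in SKLMS1. The HOXB median of RKN was 2.36 without SKN and 0.95 without SKUT1, and that of SKN was 2.23 without RKN.

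Receptor and developmental pathways added single genes. Of 36 receptor tyrosine kinases, 16 were higher in SKUT1 (median 0.40, percentile 98.9; PDGFRB 70.7, DDR2 88.4, EPHA5 50.9) and 14 lower in SKN (median -0.72, percentile 0.02). WNT genes were higher in SKUT1 in 13 of 31 (median 0.78, percentile 99.96, and 0.21 without RKN), led by the antagonist DKK1 at 517 against at most 9.92. The medians were -0.52 in RKN (percentile 1.41), despite AXIN2 at 60.0, and -0.55 in SKN (percentile 0.33, and -0.30 without SKUT1). Notch and Hedgehog genes had medians between -0.39 and 0.16 inside the central 95% of random lists, with NOTCH3 at 108 in SKUT1, LFNG at 71.7 in SKLMS1 and HES1 at 75.9 in SKN. Of 18 oncofetal and telomere genes, 6 were lower in RKN (median -0.58, percentile 1.44, and -0.22 without SKN) and 7 higher in SKN (median 0.37, percentile 97.8, 0.69 without SKLMS1), with the imprinted transcript H19 at 207 in SKUT1 and at most 0.150 elsewhere, and PEG10 at 241 in SKLMS1. Transcriptional kinases, BET proteins and HDACs were the flattest of these, with medians from -0.24 to 0.14 and EZH2, the histone methyltransferase of Polycomb, at 5.28 in SKUT1 and 17.7 to 38.4 elsewhere.

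Metabolic and ribosomal lists differed as well. Hypoxia and glycolysis genes were lower in RKN in 14 of 33 (median -0.79, below all random lists), with VEGFA at 7.94 and the glucose transporter gene SLC2A1 at 12.3 against at least 55.5 and 33.3. The SKLMS1 median of 0.55 was 0.08 without RKN. Cholesterol synthesis was higher in SKLMS1 (4 of 23, median 0.43, percentile 99.8). Metallothionein and oxidative stress genes were higher in SKUT1 in 9 of 29 (median 0.61, percentile 99.5) and lower in SKN in 9 (median -0.57, percentile 0.01, and -0.37 without SKUT1), while MT1X was 792 in RKN. Ribosomal protein genes were higher in SKN (13 of 56, median 0.70, above all random lists; RPS6 4641 against at most 2355) and lower in SKUT1 (6 of 56, median -0.52, percentile 0.01), in the same directions under all 3 other scalings. Oxidative phosphorylation medians lay between -0.27 and 0.16, with 0.15 in RKN at percentile 97.8 and -0.01 without SKUT1, 0.25 without SKLMS1 and 0.22 without SKN.

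SKUT1 had more genes highest in one line than the other lines, 557 against at most 188. The tables argue against column scaling as the whole cause, since the SKUT1 count stayed at least 1.71 times that of the next line under 3 other scalings, and against noise of low values, since the ratio was 3.32 among genes with an FPKM of 10 or more. Fibroblast-type cells in the culture, as a contaminant or in place of the named line, remain possible, because 19 of 25 fibroblast and pericyte markers were higher in SKUT1, with PI16 at 1155 and ENG at 566. Yet of all 25 members 19 reached an FPKM of 1 in at least 1 other line, and 5 belong to another list. These 19 are not the same set as the 19 higher in SKUT1. Among those higher there, PI16, PDGFRA, MEOX2 and CD34 were at most 0.142 elsewhere, the last 2 named after their values were seen. A line of mesenchymal origin could carry the same genes, and with 1 library and no reference sample these cannot be told apart; the biology of the line itself was not tested.

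COL1A1 and FN1 were listed at 0 in SKUT1, although COL1A2, the partner chain of COL1A1, was 5096 there. A loss of collagen expression as a whole is argued against, since all 11 other collagen genes of the matrix list had their highest value in SKUT1. A failed estimate of very abundant genes may explain the zeros, as quantification tools can skip a locus with too many reads. The 2 genes were the only ones listed at 0 in SKUT1 with an FPKM of 500 or more elsewhere (short RNAs left out). RKN and SKN also had such genes, ELN and MFAP5 in RKN and CRYAB and PI16 in SKN, with PI16 alone in SKLMS1. This scan cannot decide the question. ELN and PI16 were far lower in every other line than in SKUT1, so their zeros can be low expression. A gene abundant only in SKUT1 and skipped there would not reach 500 elsewhere. Failed estimate and true absence cannot be told apart without reads.

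Of the genes lowest in RKN, short RNAs left out, 11 pairs were adjacent in the order of the compared genes along the genome, against a mean of 3.55 and a highest value of 11 in 1000 random placements, with SCG5 and GREM1 or TFPI2 and GNG11 as examples. The other lines gave little of this, with 2 pairs in SKN (random highest 3), 2 in SKUT1 (random highest 4) and none in SKLMS1. The sum over the 4 lines was 15 (random mean 4.49, highest 11), which argues against random placement for the sum and rests mostly on RKN. The pairs included neighbours of the same gene family, COL4A1 and COL4A2 in RKN and APOL2 and APOL1 in SKN. Random placement makes no allowance for such neighbours, and the genes highest in a line were not compared. In SKN 1 of the 2 pairs was LRRC41 (0.0861 against at least 17.6) and UQCRH, and reads shared between UQCRH and UQCRHL are not enough to account for the low UQCRH, since their sum was also low (0.612 against at least 261, a log2 difference of -7.35). No biological explanation of the neighbours was tested, and the genes in this paragraph outside the naming rule were chosen after their values were seen.

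Several other values stand out. In SKLMS1 CDKN2A (0.549), CDKN2B (0.00887, chosen after its value was seen) and MTAP (listed at 0), which lie side by side, were all under an FPKM of 1. CDKN2A (0.125) and CDKN2B (0.0108) were under 1 in SKN too, where MTAP was 17.9. RPS28 was 146 in RKN, 211 in SKN, 0.370 in SKLMS1 and listed at 0 in SKUT1, and its pseudogenes make all 4 values uncertain. HLA-C was 4.82 in SKUT1 and at most 0.0705 elsewhere, and is as uncertain as the other HLA values.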
